A study of Rattus norvegicus with 21 samples.

How the data were processed

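RNA was sequenced from Sprague Dawley rat pancreatic islets in 21 libraries from 3 separate islet preparations, each pooled from 8 rats and divided over the culture groups. Control islets had 11 mM glucose, and glucolipotoxic (GLT) islets had 27 mM glucose with 300 µM palmitate, for 3 h or 24 h, some with compound D or compound E at 300 nM. The labels give no structure and no target for compounds D and E. The 3 h and 24 h control, GLT and GLT with compound D groups had 3 libraries each, 1 per preparation. 24 h GLT with compound E had 2 libraries (preparations 1 and 2) and 3 h GLT with compound E had 1 (preparation 2).

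Per the labels, the authors mapped paired 100 bp reads to rn5 with TopHat2 2.0.3 and Bowtie2 2.0.0, counted reads per gene with HTSeq, applied the DESeq variance-stabilizing transformation and modelled donors as a random effect. The deposited values are counts per gene, not normalized, for 17025 genes and 5 entries that name no gene. The labels state neither the strand setting nor the annotation, and whether a read pair counted once was not stated. The 5 entries without a gene were left out of library sizes and tests: reads outside annotated genes made up 10.3% to 18.7% of each column, reads with more than 1 alignment 4.92% to 23.4%, and ambiguous reads 0.161% to 2.32%.

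The deposited sample sheet and the sample records give different groups for 6 of the 21 libraries, those numbered 2 and 3 in each preparation. The record names condition 2 as 24 h control and condition 3 as 3 h GLT, and the sheet names them the other way round. The groups of the sample records were taken as the main labels before the data were examined. The sheet's labels were added after seeing the data, and every comparison that they change was run with both.

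Depth was 22.3 to 40.2 M counts in genes per library (median 27.8 M). The 2 insulin genes took 9.32% to 45.9% of the counts, and TMM factors ran from 0.682 to 1.32. With 3 counts as the floor, the detection limit lay near 0.1 CPM (counts per M counts in genes, scaled by TMM). Replicates differed by more than counting error: the lowest chi-square per degree of freedom between libraries of a group was 29.0. Residuals of libraries of the same preparation, taken from a fit of conditions alone, had a mean correlation of 0.331 (0.194, 0.373 and 0.425 in preparations 1, 2 and 3). The value between preparations, -0.165, follows from this, since the residuals of a condition sum to 0 over the preparations. The preparation was therefore kept as a block in every test, as the design gives it.

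Genes were tested with edgeR 4.0.16 in R 4.3.3. The fit held all 21 libraries, with a term per condition and per preparation, TMM scaling, and genes kept by filterByExpr (12576 genes tested). The quasi-likelihood test was 2-sided, and a gene passed at a Benjamini-Hochberg (BH) adjusted p below 0.05. Fold changes are fitted log2 values with standard errors (SE). Differences between effects (24 h against 3 h) were tested as interaction terms in the same fit.

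Gene lists written before the data were examined (20 pathway lists and 10 cell type marker lists, 657 of 684 symbols matched) were tested with camera (limma 3.58.1) on voom values at the preset correlation of 0.01 between genes, with BH over the 20 pathway lists. A second camera p used a correlation estimated from the data. List members were counted after adjustment over all genes, and again after adjustment over the list alone. The named genes were fixed by rule: in each comparison, the 8 genes with the largest rise and the 8 with the largest fall among those that passed, with the same direction in every preparation and at least 5 CPM in 1 group, and in each list up to 4 members that passed, by smallest adjusted p (up to 2 of the most abundant where none did). Not every gene that the rule gives is named. Hormone genes are named in any case.

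Whether a compound moved genes back was measured across preparations, so that no library entered both sides: the GLT difference in one preparation was correlated with the compound's difference in another, over all ordered pairs. The value with no compound effect was taken from 20 simulated data sets, since the 24 h GLT group still ties the sides together through the choice of genes. The single 3 h library with compound E was compared with the disputed libraries of its preparation without a test, each list's median being placed among 10000 random lists matched on expression.

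The pipeline was tested on simulated data with the real depths and spread. Of genes with a set change of 2-fold, 23.9% passed for compound D and 16.4% for compound E against 24 h GLT, and of those with a 4-fold change 80.3% and 74.2%. With no change set, 0 genes passed in either.

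The disputed libraries were placed by genes from a fit of the 15 undisputed libraries: 302 genes that differed between 24 h and 3 h under GLT with compound D as a time scale, and the 3 genes (Txnip and Rgs16 among them) that differed between 3 h GLT with compound D and 3 h control as a GLT scale. This check was chosen after the conflict was seen.

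The alternatives planned before the data were examined were DESeq2 1.42.0, RLE size factors, library size only, no filter, a stricter filter of 5 CPM, limma with a random preparation effect, only the groups compared, no replicate block, and each preparation left out in turn. Added after seeing the data were the sheet labels, 3 libraries that stood apart left out singly and together, a term for a split of the libraries by ambiguous reads at 1.5%, and compound D with libraries of 2 preparations. No reads, proteins or islet function data were analysed here.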

Results

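Rat islets in 3 pooled preparations were cultured under control or glucolipotoxic (GLT) conditions for 3 h or 24 h, with or without compound D or compound E. The deposited sample sheet and the sample records name 6 of the 21 libraries differently: condition 2 is 24 h control in the records and 3 h GLT in the sheet, and condition 3 the reverse. Comparisons that use neither condition come first, and the others are given under both readings. Values in parentheses are log2 fold changes with their standard errors, from edgeR's quasi-likelihood test with BH adjustment. Groups without compound E had 1 library in each preparation, so n = 3 unless stated.

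Genes measured in the 15 undisputed libraries placed the disputed ones. Time was read from 302 genes that differed between 24 h and 3 h of GLT with compound D, among them Hmox1, the heme oxygenase gene (2.62, SE 0.36), and Gsta3, a glutathione transferase gene (2.91, SE 0.39), which rose. Nr4a3, an immediate early nuclear receptor gene (-4.34, SE 0.71), and Tek, an endothelial receptor gene (-2.62, SE 0.37), fell. On this scale, with 3 h GLT with compound D at 0% and 24 h GLT with compound D at 100%, 3 h control lay at 14.4% (SD 7.9), 24 h GLT at 60.6% (SD 6.6), 24 h GLT with compound E at 64.2% (n = 2) and 3 h GLT with compound E at -7.8% (n = 1). Condition 2 lay at -5.2% (SD 5.4) and condition 3 at 65.6% (SD 1.5). The GLT scale held only 3 genes, Txnip and Rgs16 among them, with 3 h control at 0% and 3 h GLT with compound D at 100%. Condition 2 lay at 55.6% (SD 3.1) and condition 3 at 0.1% (SD 2.2), while 24 h GLT, an undisputed group, lay at 42.5% (SD 6). All 6 disputed libraries lay nearer the time and the GLT state of the sheet than those of the record. The GLT scale is coarse and mixes GLT with compound D, which raises Txnip itself: 24 h GLT with compound D lay at 73.6% (SD 13.9). Of the 9 undisputed GLT libraries outside its references, 3 lay above its midpoint, all with compound D.

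**Figure D1:**
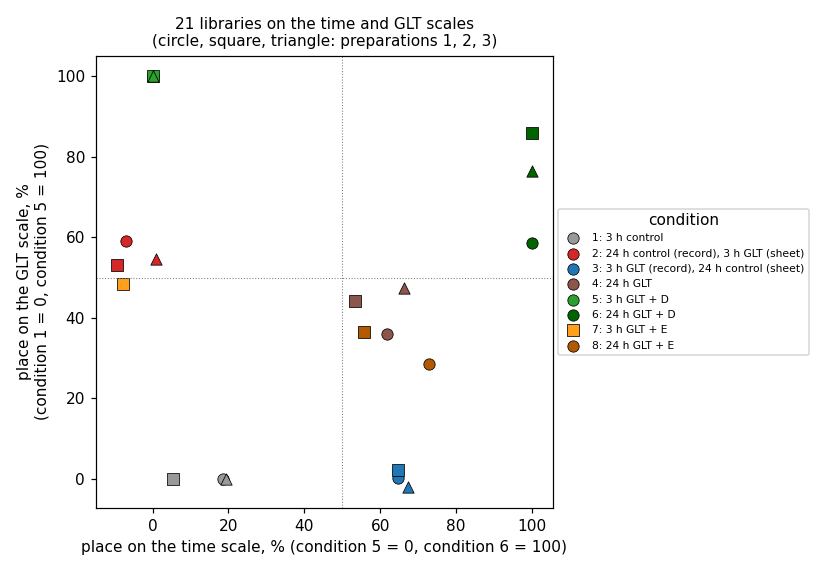
Place of each of the 21 libraries on a time scale (x, %) and a GLT scale (y, %), both built from undisputed libraries, with colours for conditions and symbols for preparations. Condition 2 lies with the 3 h libraries and condition 3, near 0.1% on the GLT scale, has the time place of the 24 h libraries.

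Under 24 h GLT, compound D lowered and raised genes in similar numbers. Gpr50, a melatonin receptor-related gene, went from 7.61 CPM with GLT to 0.157 CPM with compound D (-5.53, SE 0.72). Tph1, the serotonin synthesis enzyme gene (-5.81, SE 0.78), the zinc finger gene Plagl1 (-3.63, SE 0.36), the drug efflux pump gene Abcb1a (-3.47, SE 0.42), the activin antagonist gene Fst (-3.40, SE 0.57) and the cytokine subunit gene Il23a (-3.37, SE 0.26) also fell. The largest rises were those of Mt3, a metallothionein gene (3.16, SE 0.79), the potassium channel gene Kcnn2 (2.07, SE 0.21), the cation channel gene Trpm5 (2.06, SE 0.35) and Txnip, the glucose-responsive thioredoxin inhibitor gene (2.04, SE 0.35). Tph1 and Gpr50 had 18 and 16 reads in the 3 compound D libraries together, so their folds rest on low counts. Mt3 varied widely with compound D (mean 38.0 CPM, SD 55.3). In all, 513 of 12576 genes passed, 247 higher and 266 lower, and 294 of them changed at least 2-fold.

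Endoplasmic reticulum (ER) chaperone genes were the clearest group. Of 29 genes on the list of ATF6 and XBP1 targets, 8 fell and 0 rose (18 fell when adjusted over the list alone). Hspa5, which encodes the main ER chaperone BiP, fell from 5954 to 2777 CPM (-1.10, SE 0.14), and Hsp90b1 (-0.83, SE 0.16), the disulfide isomerase gene Pdia4 (-0.75, SE 0.15) and the chaperone gene Hyou1 (-0.75, SE 0.15) fell with it. The list as a whole was lower by camera (median -0.48, adjusted p = 1.24e-15; adjusted p = 0.0413 with an estimated correlation). Among 32 immediate early genes 9 fell and 1 rose (15 and 1 adjusted over the list alone). Nr4a2 (-2.07, SE 0.32), Klf4 (-2.04, SE 0.37) and Sik1 (-1.81, SE 0.36) were among those that fell (adjusted p = 2.06e-06 for the list; adjusted p = 0.405 with an estimated correlation).

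Of 28 beta cell identity genes 3 rose with compound D and 0 fell (4 adjusted over the list alone): Trpm5, the islet transcription factor gene Rfx6 (0.67, SE 0.15) and the urocortin gene Ucn3, a marker of mature beta cells (0.94, SE 0.24), with adjusted p = 8.62e-04 for the list and adjusted p = 0.312 with an estimated correlation. Mean log2 levels of 7 of the 10 marker lists of other cell types were higher too, red cell (-0.68 against -1.28), macrophage (0.21 against -0.28), Schwann cell (0.00 against -0.31) and delta cell markers (0.02 against -0.18) among them. The integrated stress response list divided, 3 up and 3 down. The stress-induced factor gene Atf3 (-1.89, SE 0.32) and Ppp1r15a, a regulator of translation (-1.12, SE 0.23), fell, while the serine synthesis gene Phgdh rose (0.84, SE 0.16). Of 26 apoptosis regulators 3 fell, Casp12 (-2.10, SE 0.48), which encodes a caspase, among them. Ins1 (0.09, SE 0.63) and Ins2 (0.33, SE 0.56) did not pass. The count depended on the preparations: without preparation 1 it was 0, without preparation 2 it was 234, without preparation 3 it was 87, and without the compound D library of preparation 2 it was 144.

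**Figure D2:**
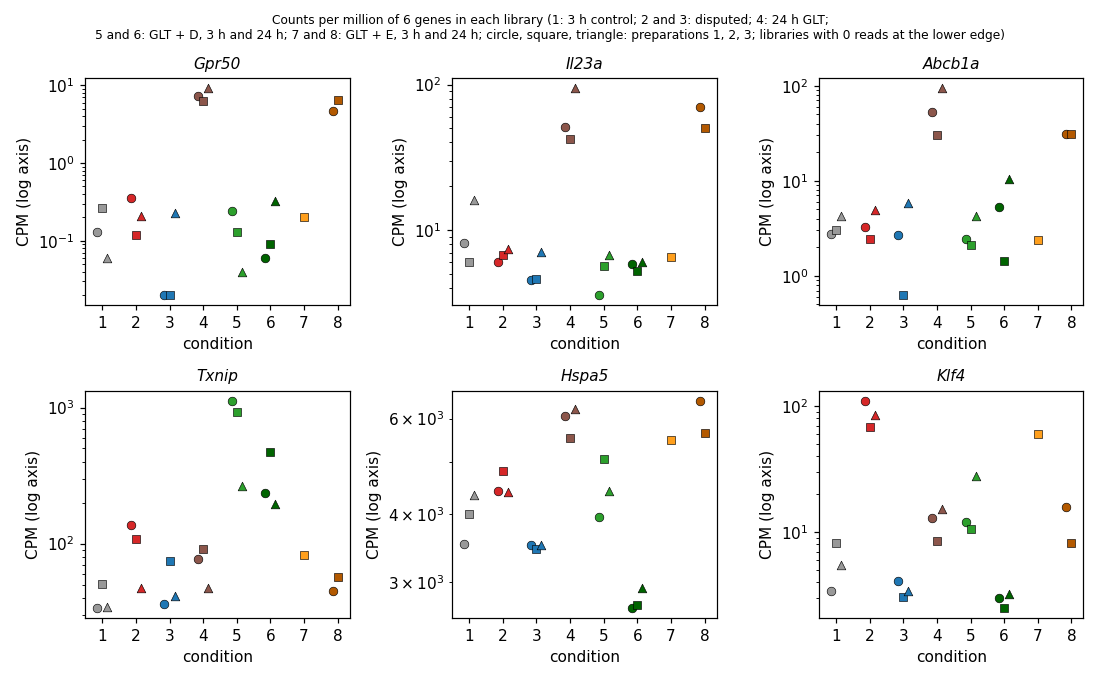
CPM on a log axis (y) of Gpr50, Il23a, Abcb1a, Txnip, Hspa5 and Klf4 in each library by condition (x), 1 point per library with a symbol per preparation (libraries with 0 reads at the lower edge). Il23a averaged 62.5 CPM in 24 h GLT (condition 4) and 60.0 CPM in 24 h GLT with compound E (condition 8), against 5.69 CPM in 24 h GLT with compound D (condition 6).

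Compound E at the same dose and time called no gene. Against 24 h GLT, 0 of 12576 genes passed edgeR's test (n = 2 against 3), 0 passed DESeq2, and 813 had an unadjusted p under 0.05. Txnip (-0.75, SE 0.39), Hspa5 (0.05, SE 0.16), Ins1 (1.31, SE 0.69) and Ins2 (1.55, SE 0.63) did not pass. On the 513 genes that passed for compound D, the median change in the direction of compound D was 1.11 for compound D and 0.08 for compound E. The 95% interval of compound E held 0 for 492 of them. These genes were picked with the same libraries, which raises the compound D side. The 234 genes that passed for compound D without preparation 2 were therefore read in preparation 2, where their median was 1.39 with compound D and -0.02 with compound E, and compound E lay below compound D for 97.9% of them. The lists of mitochondrial respiratory chain genes (adjusted p = 2.35e-05; adjusted p = 0.811 with an estimated correlation) and oxidative stress genes (adjusted p = 0.00429; adjusted p = 0.811 with an estimated correlation) were higher as groups with 0 members past the test. Library size only lowered the median of all genes by -0.39 in this comparison. Without preparation 2 the only compound E library left was one that stood apart, and 3241 genes passed. Without preparation 1 or 3, 0 passed.

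The direct test of compound E against compound D (n = 2 against 3) called 378 genes, 230 higher and 148 lower with compound E. Gpr50 (5.24, SE 0.78), Fst (3.66, SE 0.60), the lymphocyte activation gene Cd69 (3.66, SE 0.82) and Il23a (3.59, SE 0.28) were higher with compound E. Txnip (-2.79, SE 0.42) was lower. Chaperone genes were higher with compound E, 10 of 29 (23 adjusted over the list alone), among them Hspa5 (1.15, SE 0.16), the degradation factor gene Derl3 (2.08, SE 0.30) and the disulfide isomerase gene P4hb (0.97, SE 0.15), with adjusted p = 5.85e-16 for the list and adjusted p = 0.043 with an estimated correlation. Of 32 immediate early genes, 6 were higher, Fosl1 (2.19, SE 0.34) and Klf4 (2.13, SE 0.41) among them, and 1 lower (18 and 1 adjusted over the list alone), with adjusted p = 4.21e-08 and adjusted p = 0.37 with an estimated correlation. Library size only shifted the median of all genes by -0.39 and gave 236 genes, 24.6% higher in place of 60.8%. A fit of only the groups compared called 0 genes, and a term for the split of the libraries by ambiguous reads left 165. The compound D libraries of preparations 1 and 3 lay above that split and both compound E libraries below it, so the split is partly mixed with this comparison. Rn45s, the ribosomal RNA precursor gene, took 7.23% of counts with compound D and 2.38% with compound E in preparation 1. In preparation 2 it took 1.56% and 2.05%. The insulin genes took 11.7% with compound D and 42.6% with compound E in preparation 1, and 43.3% and 35.3% in preparation 2. The count was 46 without the compound E library of preparation 1, 0 without preparation 1, 4543 without preparation 2 and 101 without preparation 3.

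**Figure D3:**
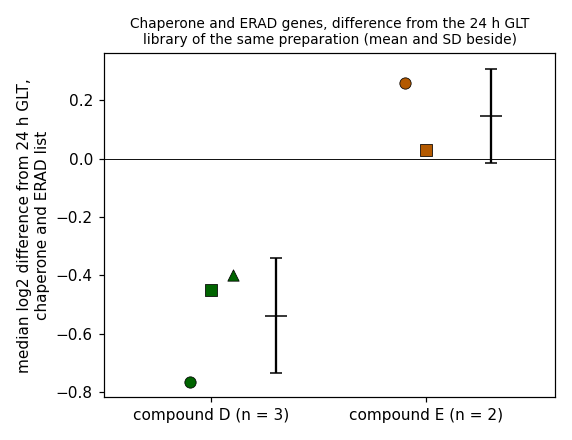
Median log2 difference (y) of the 29 chaperone genes between each compound library and the 24 h GLT library of its preparation, with mean and SD beside. The compound D values are -0.76, -0.45 and -0.40 in preparations 1, 2 and 3, and the compound E values 0.26 and 0.03 in preparations 1 and 2.

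At 3 h, 13 genes passed between GLT with compound D and 3 h control, 12 higher and 1 lower. Txnip, a glucose-responsive gene, rose 17.4-fold (4.12, SE 0.38), Ttc25, a cilium component gene, by 2.52 (SE 0.40), and the G protein regulator gene Rgs16 by 2.38 (SE 0.27). Cpt1a, the gate of mitochondrial fatty acid oxidation, rose too (1.06, SE 0.16). At an unadjusted p under 0.05 there were 817 genes, and DESeq2 called 108. The cholesterol synthesis list was higher with 0 members past the test over all genes and 6 of 25 adjusted over the list alone (adjusted p = 1.08e-12; adjusted p = 0.149 with an estimated correlation). Without preparation 1 or 3 the count was 1, without preparation 2 it was 103, and with library size only it was 5. Without the compound E library of preparation 1, which shares the estimate of spread, it was 25. A fit of the 15 undisputed libraries alone called 3 genes, 2 higher and 1 lower, with Txnip and Rgs16 among them.

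The change of the GLT effect between 3 h and 24 h is the same contrast under both readings, and 9 genes passed. Abcb1a (4.42, SE 0.58), Il23a (3.97, SE 0.36), the annexin gene Anxa3 (2.84, SE 0.41) and the amino acid transaminase gene Bcat1 (1.97, SE 0.27) had larger GLT effects at 24 h. Ypel4 (-2.97, SE 0.36), the receptor gene Gprc5b (-1.61, SE 0.17) and the organelle biogenesis gene Hps4 (-1.39, SE 0.23) had lower ones, as did P2rx3 and Dos. At an unadjusted p under 0.05 there were 1050 genes, and DESeq2 called 111. Immediate early genes as a list shifted down (adjusted p = 1.27e-04; adjusted p = 0.552 with an estimated correlation) with 0 of 32 past the test and 3 adjusted over the list alone. Without preparation 1 or 3 no gene passed, and library size only moved the median of all genes by 0.36 and left 5 genes, 80% higher in place of 44.4%.

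The effect of 24 h GLT depended on which condition served as the 24 h control. With the sheet's labels (condition 3), GLT raised Gpr50 (6.57, SE 0.79), Fst (4.45, SE 0.61), Abcb1a (4.42, SE 0.44) and the nuclear receptor gene Rorb (3.62, SE 0.56). The size of the Gpr50 change was uncertain, running from 3.48 to 10.55 over the alternatives, and that of Fst ran from 2.51 to 5.2. The interferon-induced genes Oas1a (-4.22, SE 0.91), Mx2 (-3.59, SE 0.92) and Irf7 (-3.35, SE 0.84) fell. Of 40 integrated stress response genes 9 rose and 0 fell (13 adjusted over the list alone), led by Atf3 (2.57, SE 0.33), Ppp1r15a (2.82-fold, SE 0.23 in log2) and the cystine transporter gene Slc7a11 (2.07, SE 0.35), with adjusted p = 8.02e-08 and adjusted p = 0.0595 with an estimated correlation. Of 23 oxidative stress genes 4 rose (15 adjusted over the list alone), Srxn1 (1.36, SE 0.23) and Txnrd1 (0.78, SE 0.14) first, with adjusted p = 5.58e-09 and adjusted p = 0.0595 with an estimated correlation. Beta cell identity genes went down, 5 of 28 (10 adjusted over the list alone), with Trpm5 (-1.89, SE 0.35), the amylin gene Iapp (-0.78, SE 0.19) and Rfx6 (-0.59, SE 0.15) among them (adjusted p = 6.95e-06; adjusted p = 0.0595 with an estimated correlation). Mean log2 levels of 9 of the 10 marker lists of other cell types were also lower in condition 4 than in condition 3, among them alpha cell (-0.14 against 0.36), delta cell (-0.18 against 0.45), PP cell (-0.48 against 0.48), stellate cell (0.03 against 0.54), Schwann cell (-0.31 against 0.25) and macrophage markers (-0.28 against 0.24), while acinar markers were not (0.17 against 0.10). The fatty acid gene Acot2 (2.16, SE 0.22) and the chaperone gene Hspa5 (0.77, SE 0.14) rose. In all 751 genes passed, 416 higher and 335 lower, with 15 without preparation 1, 455 without preparation 2, 90 without preparation 3, and 219 without the library of condition 3 in preparation 2. Library size only gave 292 genes, 67.8% higher in place of 55.4%.

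With the record's labels (condition 2 as 24 h control), 24 h GLT called 1072 genes, 457 higher and 615 lower. Gpr50 (5.05, SE 0.71), Cd69 (4.23, SE 0.83) and Abcb1a (3.97, SE 0.43) were among the largest rises. Fam46b (-5.34, SE 0.70), the hemoglobin gene Hba-a2 (-5.13, SE 0.58) and the collagen gene Col13a1 (-4.65, SE 0.64) fell most. Immediate early genes fell, 13 of 32 with 1 rising (19 and 1 adjusted over the list alone), Nr4a2 (-2.74, SE 0.32) and Klf4 (-2.88, SE 0.37) among them, with adjusted p = 2.69e-11 and adjusted p = 0.324 with an estimated correlation. The endothelial genes Plvap (-2.96, SE 0.46) and Tek (-1.88, SE 0.33) fell. The peroxisome gene Pex11a (1.62, SE 0.33) rose with others of the list of fatty acid oxidation genes and PPAR targets (8 of 29 rose, 11 adjusted over the list alone, with adjusted p = 2.93e-04 and adjusted p = 0.324 with an estimated correlation). Library size only moved the median of all genes by 0.25 and made 71.7% of 633 genes higher in place of 42.6%. The count was 21 without preparation 1 and 83 without preparation 3.

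Condition 2 against condition 1 (3 h GLT by the sheet, 24 h control by the record, both against 3 h control) called 290 genes, 247 higher and 43 lower. Fam46b (5.18, SE 0.69), the metallothionein genes Mt1a (4.66, SE 0.87) and Mt2A (4.37, SE 1.03) and the immediate early gene Klf4 (3.90, SE 0.39) rose most, and the clock output gene Dbp (-1.52, SE 0.26) fell most. Of 32 immediate early genes 16 rose (24 adjusted over the list alone), Klf4 and Nr4a2 (3.02, SE 0.33) first, with adjusted p = 8.3e-26 and adjusted p = 0.0317 with an estimated correlation. The fatty acid genes Acot2 (1.77, SE 0.22) and Cpt1a (1.04, SE 0.16) rose among 29 oxidation genes, of which 3 passed (4 adjusted over the list alone; adjusted p = 0.00125; adjusted p = 0.276 with an estimated correlation). Library size only moved the median of all genes by -0.28 and left 67 genes, 73.1% higher in place of 85.2%. Without preparation 1 the count was 7 and without preparation 3 it was 57.

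Condition 3 against condition 1 (24 h control by the sheet, 3 h GLT by the record) called 87 genes, 32 higher and 55 lower. Dlk1, a growth factor-like gene (4.17, SE 0.59), and the matrix genes Cilp (2.61, SE 0.51) and Lum (2.13, SE 0.37) rose, and Hba-a2 (-3.58, SE 0.54), the bone matrix gene Dmp1 (-3.46, SE 0.40) and the endothelial gene Plvap (-2.37, SE 0.45) fell. Cell cycle genes fell, 4 of 39 (18 adjusted over the list alone, where 2 rose), with Cdk1 (-2.05, SE 0.40) and Kif11 (-1.49, SE 0.31) first (adjusted p = 1.65e-12; adjusted p = 0.157 with an estimated correlation). Mean log2 levels of red cell (-1.10 against 0.78) and endothelial markers (-0.37 against 0.62) were lower in condition 3, and those of stellate cell markers higher (0.54 against -0.06). Hba-a2 and Dmp1 also fell between 3 h and 24 h of GLT with compound D (-3.24, SE 0.56 and -3.21, SE 0.37), a comparison without disputed libraries. Library size only shifted the median of all genes by -0.11 and made 9.4% of 32 genes higher in place of 36.8%. The count was 1 without preparation 1, 7 without preparation 3, 22 without the library of condition 3 in preparation 2, and 148 without the compound E library of preparation 1, which shares the estimate of spread.

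The 3 h effect of compound D also turned on the labels. By the sheet (condition 5 against condition 2) 62 genes passed, 8 higher and 54 lower. Txnip (2.92, SE 0.36), Ttc25 (2.08, SE 0.39) and the arrestin-domain gene Arrdc4 (1.84, SE 0.30), like Txnip a glucose-responsive gene, rose. Fam46b (-3.17, SE 0.59), the tachykinin gene Tac1 (-2.78, SE 0.40), Nr4a2 (-2.66, SE 0.32) and Klf4 (-2.45, SE 0.37) fell. Immediate early genes were lower, 4 of 32 (19 adjusted over the list alone, where 1 rose), with adjusted p = 3.15e-23 and adjusted p = 0.0461 with an estimated correlation. By the record (condition 5 against condition 3) 872 genes passed, 502 higher and 370 lower: Nr4a3 (4.58, SE 0.61), Txnip (3.81, SE 0.37) and Hba-a2 (3.56, SE 0.54) rose, and Dlk1 (-3.73, SE 0.58) and the matrix protease gene Mmp9 (-3.69, SE 0.78) fell. Cholesterol synthesis genes rose by the record, 14 of 25 (21 adjusted over the list alone), Insig1 (2.51, SE 0.32) and Cyp51 (1.45, SE 0.23) first (adjusted p = 4.05e-14; adjusted p = 0.19 with an estimated correlation). In that comparison red cell (0.97 against -1.10) and endothelial markers (0.53 against -0.37) were higher and stellate cell markers lower (-0.34 against 0.54). Without preparation 1 the counts were 0 by the sheet and 7 by the record, without preparation 2 they were 45 and 1368, and without preparation 3 they were 14 and 76, and without the library of condition 3 in preparation 2 the record gave 490. Library size only shifted the medians by 0.32 and 0.15 and gave 14 genes by the sheet (50% higher in place of 12.9%) and 353 by the record (84.4% in place of 57.6%). Fits of only the groups compared called 343 genes by the sheet and 0 by the record.

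The compound D effect at 24 h differed from that at 3 h for 4 genes by the sheet. Gprc5b was higher (1.52, SE 0.17), and Anxa3 (-3.03, SE 0.41), Il23a (-3.01, SE 0.35) and Bcat1 (-1.69, SE 0.27) were lower. By the record 968 genes passed, 472 higher and 496 lower, with Mmp9 (4.21, SE 1.05) the largest rise and Nr4a3 (-6.63, SE 0.83) and Gpr50 (-6.37, SE 1.30) the largest falls. Without preparation 1 the counts were 0 by the sheet and 12 by the record, without preparation 2 they were 7 and 620, and without preparation 3 they were 0 and 277. Without the library of condition 3 in preparation 2 the sheet gave 13, and library size only moved the record's median by -0.15 and gave 361 genes, 31.9% higher in place of 48.8%.

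Islets with GLT and compound D for 24 h differed from control in fewer genes by the sheet than by the record. Against condition 3, 1547 genes had an unadjusted p under 0.05, 12 of 20 lists passed camera (2 with an estimated correlation), and 90 genes passed, 58 higher and 32 lower: the phosphatase gene Alpl (2.70, SE 0.45), the lipase inhibitor gene Angptl4 (2.67, SE 0.55) and Txnip (2.51, SE 0.35) rose, and Plagl1 (-2.43, SE 0.34) and the Wnt antagonist gene Sfrp5 (-2.25, SE 0.30) fell. Integrated stress response genes were higher, 5 of 40 (17 adjusted over the list alone), Phgdh (1.18, SE 0.16) and Psat1 (1.01, SE 0.19) first, with adjusted p = 3.27e-16 and adjusted p = 0.00316 with an estimated correlation. Oxidative stress genes were higher, 5 of 23 (13 adjusted over the list alone), with Osgin1 (2.03, SE 0.25) and the autophagy receptor gene Sqstm1 (1.10, SE 0.17) first, with adjusted p = 5.51e-12 and adjusted p = 0.0317 with an estimated correlation. Marker lists of other cell types differed as well, with alpha cell (-0.05 against 0.36), delta cell (0.02 against 0.45), PP cell (-0.31 against 0.48) and stellate cell markers (-0.06 against 0.54) lower than in condition 3. Against condition 2, 1576 genes passed, with Alpl (3.21, SE 0.46) among the largest rises and Fam46b (-6.59, SE 0.77) and Nr4a3 (-5.46, SE 0.63) the largest falls. Without preparation 1 the counts were 0 by the sheet and 338 by the record, and without preparation 3 they were 4 and 491. The sheet's count was 36 without preparation 2, 38 without the library of condition 3 and 48 without that of condition 6 in preparation 2, and 158 without the compound E library of preparation 1. Library size only gave 23 genes by the sheet (82.6% higher in place of 64.4%) and 1302 by the record (75.5% in place of 47.3%), where it moved the median of all genes by 0.25.

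With compound E, islets under 24 h GLT remained far from control by either reading (n = 2). By the sheet 1066 genes passed, 676 higher and 390 lower, led by Gpr50 (6.28, SE 0.85), Fst (4.72, SE 0.66) and Abcb1a (4.08, SE 0.47), with Oas1a the largest fall (-4.88, SE 1.20). The size of the Gpr50 change was uncertain here too, from 3.12 to 10.31 over the alternatives. Of 23 oxidative stress genes 14 rose (18 adjusted over the list alone), Osgin1 (1.87, SE 0.27) and Sqstm1 (1.25, SE 0.19) first (adjusted p = 2.67e-10; adjusted p = 0.101 with an estimated correlation). Alpha cell (-0.12 against 0.36), delta cell (-0.14 against 0.45) and PP cell markers (-0.02 against 0.48) were lower than in condition 3. By the record 992 genes passed, with Gpr50 (4.76, SE 0.75) and Cd69 (4.72, SE 0.88) the largest rises and the somatostatin receptor gene Sstr1 (-4.92, SE 0.76) the largest fall. Without the compound E library of preparation 1 the counts were 42 by the sheet and 63 by the record, and without preparation 2, where that library alone was left, they were 4138 and 4422. Without preparation 1 they were 4 and 0, without preparation 3 they were 195 and 121, and without the library of condition 3 in preparation 2 the sheet gave 271. Library size only moved the medians by -0.31 and -0.14 and gave 209 genes by the sheet (38.8% higher in place of 63.4%) and 237 by the record (33.8% in place of 53.6%).

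Compound D opposed the 24 h GLT change by the sheet and less clearly by the record, and compound E did not. By the sheet, of the 751 genes that 24 h GLT changed, compound D moved 280 (37.3%) in the opposite direction past the test and 0 in the same direction, against a mean of 0.05 genes in simulations with no compound effect, which share the 24 h GLT libraries in the same way. Across preparations the GLT and compound D changes of these genes had a mean correlation of -0.785 (SD 0.050 over 6 ordered pairs), against -0.192 simulated with no compound effect. In islets with GLT and compound D, 43 of the 751 still passed against control, and the median change over all 751 was 0.28 in place of 0.99. With compound E, 478 still passed, the median over all 751 was 0.98, and the correlation was -0.086 (SD 0.048) against -0.186 with no effect. By the record, compound D moved 113 of 1072 genes (10.5%) back and 36 further, the correlation was -0.359 (SD 0.069) against -0.183, and 568 genes still passed. Compound E gave -0.130 (SD 0.027) against -0.174, with 606 genes still past the test. The pooled correlation, where both sides share the 24 h GLT libraries, hardly set compound D apart by the record. It was -0.437 against -0.411 with no effect, and the pooled covariance -0.587 against -0.35. By the sheet the pooled correlation for compound D was -0.862 against -0.431. Gpr50, Abcb1a, Fst and Il23a rose with GLT by the sheet and fell with compound D. The effects of compounds D and E across preparations had a correlation of 0.170 (SD 0.102 over 4 ordered pairs) over 513 genes. The value simulated with no effect, -0.009, used these same genes and did not choose them anew. It leaves out the tie through the choice of genes, so it cannot show whether 0.170 exceeds that tie. Of the 234 genes that passed for compound D without preparation 2, 48.7% moved in its direction with compound E in preparation 2.

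**Figure D4:**
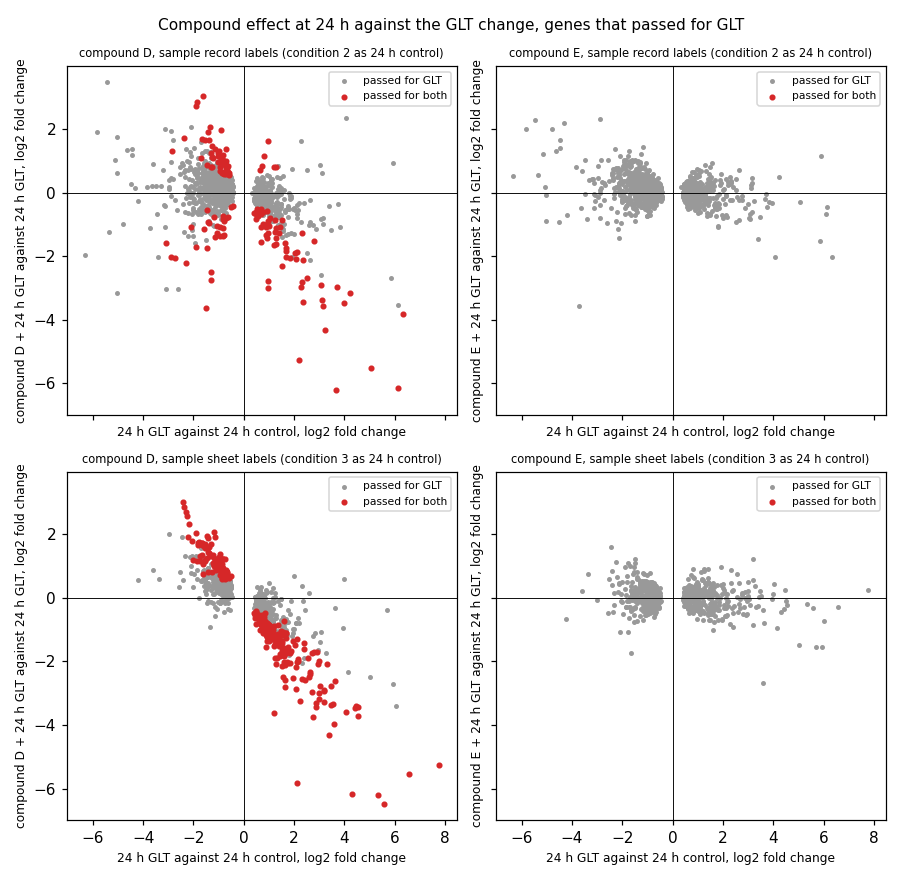
Compound effect at 24 h (y, log2 fold change) against the GLT change (x, log2 fold change) for genes that passed for GLT, with genes that passed for both in red, for compound D and compound E under the record's labels (top) and the sheet's labels (bottom). The 24 h GLT libraries enter both axes, which tilts each cloud downward; under the sheet's labels all 280 red points lie on opposite sides of 0.

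The single 3 h library with compound E (preparation 2) was compared with the disputed libraries of its preparation without a test. Against condition 2 (3 h GLT by the sheet) 7 of 20 lists had medians outside the central 95% of random lists, and against condition 3 (3 h GLT by the record) 7 did. The compound D library of the same preparation gave 7 and 9, so these counts are not particular to compound E, although the lists were not the same. Against condition 2 the 7 list medians with compound E were 0.37 for NF-kB and cytokine genes, 0.17 for disallowed and dedifferentiation genes, 0.17 for glycolysis and hypoxia genes, 0.15 for immediate early genes, 0.08 for chaperone genes, 0.05 for the respiratory chain and -0.10 for the integrated stress response. With compound D they were -1.04 for immediate early genes, the opposite sign, and -0.26 for the integrated stress response. Its others were 0.39 for cholesterol synthesis, 0.32 for glucose-responsive and 0.32 for cell cycle genes, -0.23 for p53 targets and -0.18 for insulin granule exocytosis. Log2 differences over all genes had an SD of 0.346 against condition 2 and 1.22 against condition 3. The condition 3 library used here is one that stands apart, and the compound D library of the same preparation gave 0.487 and 1.18, so the width is not particular to compound E. No gene was tested, since 1 library has no spread of its own.

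Change over time without disputed libraries was read from GLT with compound D at 24 h against 3 h, where 133 genes rose and 169 fell. The length of exposure to GLT and to compound D differs here together with time in culture, so culture time alone was not isolated. On the scale built from these genes, 24 h GLT without compound D lay at 60.6%. Cell cycle genes fell, 9 of 39 (23 adjusted over the list alone), Prc1 (-1.77, SE 0.25) and Rrm2 (-1.79, SE 0.30) first, with adjusted p = 2.14e-12 and adjusted p = 0.106 with an estimated correlation. Cholesterol synthesis genes fell, 7 of 25 (18 adjusted over the list alone), led by Insig1 (-1.56, SE 0.32), with adjusted p = 6.56e-10 and adjusted p = 0.111 with an estimated correlation. Of 23 oxidative stress genes 4 rose (13 adjusted over the list alone), Hmox1 first. Of 15 endothelial markers 3 fell (Tek, Plvap and Kdr; 8 adjusted over the list alone; adjusted p = 1.49e-05; adjusted p = 0.636 with an estimated correlation), and of 6 red cell markers 3 fell (Hba2, Hbb-b1 and Hba-a2; 5 adjusted over the list alone; adjusted p = 8.68e-04; adjusted p = 0.168 with an estimated correlation).

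The hormone genes Ins1, Ins2, Gcg (glucagon) and Sst (somatostatin) were tested in all 17 distinct comparisons of conditions. Of these 68 tests 0 passed edgeR, 5 had an unadjusted p under 0.05, and 0 passed DESeq2. The share of the counts in Ins1 and Ins2 ran from 9.32% to 45.9% between libraries.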

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

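The effect of GLT at 24 h differed from that at 3 h, by the interaction term, for 9 genes (4 higher, 5 lower), Abcb1a and Il23a among them, and this contrast is the same under both sets of labels. Of 100 splits of the 12 libraries within preparations 14 called as many genes, and the highest of the others called 1258, so chance cannot be excluded by this count. A count of 1258 points to a structure of the libraries, and splits by culture time or treatment are among the possible ones.

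The effect of compound D at 24 h differed from that at 3 h for 968 genes by the sample records and for 4 by the sample sheet (Gprc5b, Anxa3, Il23a and Bcat1). For the record's 968, 1 of 100 splits gave as many, the real one, and the highest of the others called 558. For the sheet's 4, 10 of 100 splits did, with 2270 the highest of the others. Which of these counts holds depends on the labels of conditions 2 and 3.

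Reads with more than 1 alignment, which the comparisons do not use, made up 23.4% of the column of condition 3 in preparation 2, against 8.51% at most in the other 20 libraries, controls included. This library is 24 h control by the sheet and 3 h GLT by the record. Without it, the 24 h GLT effect by the sheet went from 751 genes to 219 and condition 3 against condition 1 from 87 to 22.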

How the results depend on the processing

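The sample sheet labels, the libraries left out because they stood apart, the library split, compound D with 2 libraries and all alternatives under the sheet's labels were chosen after seeing the data. The remaining alternatives were fixed before the data were examined. Counts are genes at an adjusted p below 0.05. Condition numbers stand for the disputed groups, and a comparison with condition 2 or 3 is named by its conditions (1 3 h control, 4 24 h GLT, 5 and 6 GLT with compound D at 3 h and 24 h, 8 24 h GLT with compound E).

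Counts fell sharply without preparation 1 or 3. Leaving out 1 preparation or 1 of the 3 libraries that stood apart at a time gave 0 to 684 genes for compound D against 24 h GLT (513 with all), 0 to 3241 for compound E against 24 h GLT (0), 0 to 4543 for compound E against compound D (378), 1 to 103 for condition 5 against 1 (13), 0 to 11 for the change of the GLT effect (9), 15 to 1037 for 4 against 3 (751), 21 to 1380 for 4 against 2 (1072), 7 to 379 for 2 against 1 (290), 1 to 148 for 3 against 1 (87), 0 to 86 for 5 against 2 (62), 7 to 1368 for 5 against 3 (872), 0 to 13 and 12 to 1371 for the change of the compound D effect by the sheet (4) and the record (968), 0 to 158 for 6 against 3 (90), 338 to 2143 for 6 against 2 (1576), 4 to 4138 for 8 against 3 (1066) and 0 to 4422 for 8 against 2 (992). The lowest came without preparation 1 in each. Compound E against 24 h GLT was 0 under every alternative except the fit without preparation 2. For compound D against 24 h GLT the median SE rose from 0.261 to 0.302 without preparation 1 and to 0.323 without preparation 3, where 87 genes passed. The highest counts with compound E came without preparation 2, where its only library is the one that stands apart and is assumed to vary like the other groups. The correlation of GLT and compound D changes ranged from -0.384 to -0.346 by the record and -0.832 to -0.751 by the sheet, that of GLT and compound E changes from -0.152 to -0.098 and -0.122 to -0.045, and that of the 2 compounds from 0.071 to 0.229. Without the 3 libraries together the counts were 13 for compound E against compound D, 35 for 5 against 1, 14 for the change of the GLT effect, 2051 for 4 against 2, 610 for 2 against 1, 171 for 3 against 1, 142 for 5 against 2, 8 for the change of the compound D effect by the sheet, 9 for 8 against 3 and 154 for 8 against 2.

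With no replicate block, so without the paired preparations, counts fell: 220 for compound D against 24 h GLT, 149 for compound E against compound D, 3 for the change of the GLT effect, 305 for 4 against 3, 604 for 4 against 2, 169 for 2 against 1, 17 for 3 against 1, 33 for 5 against 2, 426 for 5 against 3, 0 (sheet) and 516 (record) for the change of the compound D effect, 19 for 6 against 3, 1035 for 6 against 2, 518 for 8 against 3 and 587 for 8 against 2.

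DESeq2 called more: 905 for compound D against 24 h GLT, 835 for compound E against compound D, 108 for 5 against 1, 111 for the change of the GLT effect, 1285 for 4 against 3, 590 for 2 against 1, 387 for 3 against 1, 165 for 5 against 2, 1430 for 5 against 3, 87 and 1575 for the change of the compound D effect by sheet and record, 382 for 6 against 3, 1874 for 8 against 3 and 1726 for 8 against 2. Library size only called fewer: 215, 236, 5 and 5 in the first 4 of these, 292 for 4 against 3, 633 for 4 against 2, 67 for 2 against 1, 32 for 3 against 1, 14 for 5 against 2, 353 for 5 against 3, 361 for the change of the compound D effect by the record, 23 for 6 against 3, 209 for 8 against 3 and 237 for 8 against 2.

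Fits of only the groups compared went both ways: 274 for compound D against 24 h GLT, 0 for compound E against compound D, 7 for 5 against 1, 5 for the change of the GLT effect, 357 for 4 against 3, 3263 for 4 against 2, 0 for 3 against 1, 343 for 5 against 2, 0 for 5 against 3, 10 for the change of the compound D effect by the sheet, 0 for 6 against 3, 726 for 6 against 2, 0 for 8 against 3 and 183 for 8 against 2. Limma with a random preparation effect gave 16 for the change of the GLT effect, 21 for 5 against 1 and 8 for the change of the compound D effect by the sheet, and the stricter filter gave 8 for the last. A term for the library split gave 165 for compound E against compound D, 8 for 5 against 1 and 2192 for 8 against 3. In preparations 1 and 3 the libraries of conditions 5 and 6 lay above the split and those of condition 3 below it. The split is therefore also partly mixed with 5 against 3 and 6 against 3, where its term gave 697 and 87. Compound D with 2 libraries gave 264. Other counts, and all counts under RLE size factors and no filter, stayed within 1.5 times.

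With the sample sheet labels in place of the record's, 3 h GLT against 3 h control went from 87 to 290 genes, 24 h against 3 h control from 290 to 87, compound D at 3 h from 872 to 62, the change of its effect from 968 to 4, and GLT with compound D against control at 24 h from 1576 to 90. The correlation of GLT changes went from -0.359 to -0.785 for compound D and from -0.130 to -0.086 for compound E. With all tested genes in place of called ones these were -0.121 and -0.030 by the record and -0.307 and 0.025 by the sheet, the last of the opposite sign. Of the named gene results by the record, 17 changed sign. In 24 h GLT against control Fam46b became 1.62, Nr4a2 1.27 and Klf4 1.76. In 24 h against 3 h control Fam46b became -1.78, Mt1a -0.27, Mt2A -0.36, Klf4 -0.74 and Nr4a2 -0.99. In 3 h GLT against 3 h control Cilp became -0.53, Lum -0.42, Hba-a2 0.84 and Plvap 0.19. In compound D at 3 h Nr4a3 became -1.13, Hba-a2 -0.86 and Mmp9 0.14. In GLT with compound D against control at 24 h Fam46b became 0.38 and Nr4a3 0.26.

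Over all alternatives, 136 named gene results gave 2238 values, of which 1784 kept the side of the threshold, 436 lost it, 1 gained it and 17 changed sign, those above. Without preparation 1, 120 lost it. Of the gene list tests, 79 passed by the record and 62 by the sheet. Camera with an estimated correlation left 3 and 4, and fry left 37 and 34.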

Other observations

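The tests of the labels, of the compound E result, and of compound D acting on chaperone genes were chosen after those results were seen. The tests of the library split and of the insulin share on the chaperone genes, and the counts over other splits of the libraries, were set before their values were seen.

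The libraries of conditions 2 and 3 lay on the time and GLT scales where the other condition's sample record would put them. With the names of conditions 2 and 3 exchanged in the sample records, all 6 libraries would lie on the sheet's side of both scales, and 6 of 6 did, with both conditions out of place. The midpoint of the GLT scale is a weak check, since only 3 of 9 undisputed GLT libraries outside the references lay above it. Their places ran from 28.6% to 85.9%, above that of condition 3 (0.1%). The sample records as written, with time and GLT acting on the score genes as they do in the other conditions, would leave at least 4 of 6 on the record's side of the time scale, and 0 lay there, while 9 of 9 undisputed libraries outside the references lay on the side of their label. A library that stands apart (condition 3 of preparation 2) is not enough, since 0 of the 4 libraries in preparations 1 and 3 lay on the record's side. The sheet's labels are therefore the likely ones, as a hypothesis: both scales come from islets with compound D, which itself moves genes of the GLT scale, and a different response of untreated islets to time was not tested.

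Compound E called 0 genes against 24 h GLT (813 at an unadjusted p under 0.05, 0 by DESeq2) where compound D called 513. Fewer libraries of compound E stay open as a cause of the count, since fits that left compound D 2 libraries called 264, 234, 144 and 87 genes, and 0 without preparation 1. The compound E library of preparation 1 that stands apart is not enough, since the other compound E library, in preparation 2, moved the 234 compound D genes called without that preparation by a signed median of -0.015, against 1.39 for compound D. Over these genes compound E lay -1.391 from compound D, in a preparation not used to pick them. This goes with a weaker action of compound E on these genes. It is 1 library of each compound, however, and that of compound D also stands apart. The genes were picked for compound D, so they cannot show whether compound E acted on other genes. A lower potency, an inactive partner compound or loss of compound E in culture may each give a weaker action on these genes. With 1 dose and no exposure data they stay open.

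Chaperone genes were lower with compound D than with 24 h GLT alone. The split of the libraries by ambiguous reads is not enough, since the list's median was -0.477 with a term for it and -0.477 without, and 7 members passed in place of 8. A few genes taking most of the counts would shift the scaling of all genes alike. With library size only the list lay -0.504 from the median of all genes. Scaling cannot change that distance, so this setting could not test the explanation. The value shows only that the list fell relative to other genes, which a shift of all genes alike would not give. The median of all genes was 0.005 there, moved by -0.001, but this averages over preparations. The insulin share went from 23.0% with GLT to 11.7% with compound D in preparation 1, and from 25.8% to 43.3% in preparation 2. Medians were below 0 in all 3 preparations, the highest -0.399, but this restates the result that the list was picked for, so compound D acting on these genes stays an open explanation. Whether fewer unfolded proteins, fewer secretory cells or less insulin synthesis lies behind it was not tested here.

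Other splits of the same libraries were counted for each comparison of 3 libraries against 3. Such a comparison has 10 splits, too few for a share under 0.05, and in each the real one alone (1 of 10) called as many genes. The real counts were 513 for compound D against 24 h GLT, 751 and 1072 for 24 h GLT by the sheet and the record, 290 for condition 2 against 1, 62 and 872 for compound D at 3 h, 13 for GLT with compound D against control at 3 h, and 90 and 1576 for it at 24 h, with 0 in the highest of the other splits. For condition 3 against condition 1 the real split called 87 genes and the highest of the others 10. Of the 10 splits, the real one and 3 others part all 3 preparations as it does, and these 3 called 0 genes in every comparison.

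Some endothelial and red cell markers (3 of 15 and 3 of 6) fell in culture under GLT with compound D, although neither list passed with an estimated correlation (adjusted p = 0.636 and 0.168). Mean levels of both lists were also lower in 24 h GLT and compound E libraries than in 3 h libraries of the same preparations in all 5 library pairs. The pairs are not independent: preparations 1 and 2 enter more than once, and the pairs of preparation 1 share their 3 h control library. In 4 of the 5 pairs the 3 h library was a control, so time is mixed with GLT. Only the pair with compound E at both times (preparation 2) holds GLT constant (-0.81 for endothelial and -2.65 for red cell markers). What removed these transcripts was not tested here.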
